A study of Mus musculus with 18 samples.

How the data were processed

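RNA was measured by sequencing in brain tissue of Diversity Outbred mice, an outbred stock in which each animal carries its own mix of the genomes of several founder strains. The 18 libraries came from 3 tissues, the prefrontal cortex (PFC) and the tissues named MDTH and HPF in the labels, with 3 libraries from high performers and 3 from low performers in each. Libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols. The sources used here do not say which test defined high and low performers, nor what was dissected beyond the tissue names.

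The deposited table gave 1 normalized signal per gene and library, gene counts divided by normalization factors by the authors, per the name of the deposited table. STAR, Salmon and DESeq2 were named without versions or roles, per the submitters' processing notes. The genome build, the annotation and the use of strand in counting were not given in the sources used here. The table held 48440 genes, of which 17137 were at 0 in all 18 libraries, so the deposited signal had not been filtered. All 18 columns were matched to samples by the library names in the labels, and 0 columns were left unmatched. Of the gene identifiers, 48058 (99.2%) were found in the GENCODE M21 annotation of mouse build GRCm38, all with equal symbols. Coordinates are from that annotation. A symbol was lacking for 381 genes.

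Column totals ran from 50828589 to 59634490 normalized counts, a range set by the normalization. Depth was estimated from the most frequent low value of each library, taken as the worth of 1 read. It came to 41156227 to 48838302 reads in PFC, 42941006 to 47535113 in MDTH and 76705451 to 88633852 in HPF, figures that are estimates. Within 0.02 of a read, the low values that were whole reads made up 50.7% ± 8.29 (SD, n = 3) in high and 27.7% ± 0.762 (SD, n = 3) in low performers of PFC. The shares were 56.5% ± 13.6 and 30.9% ± 12.0 in MDTH, and 39.0% ± 4.66 and 34.6% ± 12.2 in HPF (SD, n = 3 each). Only low values were examined in this way. Whole reads could therefore not be recovered for all genes of any library, and tests that need counts were not run.

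Each tissue was tested alone, 3 high against 3 low libraries, with limma 3.58.1 in R 4.3.3. Values were taken as log2(normalized count + 1), genes with a mean of at least 10 over the 6 libraries were kept, and the moderated test was two-sided with a mean-variance trend. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 are said to have passed. All adjusted p-values below come from these limma fits or from limma's camera and fry tests. Log2 differences are high minus low on the log2(normalized count + 1) scale, which understates the change of low genes. Whether a difference differed between tissues was tested as an interaction in 1 limma fit to all 18 libraries with 6 group means, as were the differences between tissues. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the figures. The labels give separate samples but do not say that each library of a group came from a separate animal, so p-values measure the spread between these libraries.

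Before the data were examined, 28 gene lists were fixed for pathways, brain regions, cell types and the chromosomal neighbourhood of Gpr12. Except for the sex genes, 27 lists of at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the libraries. Limma's fry test was run beside it on all 28 lists. It allows for correlation between genes but asks whether a list's genes differ, not whether they differ more than other genes. The rule for named genes was also fixed then. It took Gpr12 in every tissue. It took the 10 genes with the smallest p higher and the 10 lower in high performers that passed and whose groups did not overlap, leaving out predicted-gene and clone names. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It also took the 2 members with the smallest p of each list that passed, and of the lists for the Gpr12 neighbourhood, orphan receptors, cAMP signalling and immediate-early genes in any case. For interactions it took 5 genes, and for tissue differences 4 members of each regional list. Genes named outside the rule are list members given as examples, or are said to have been chosen after their values were seen. Some genes that the rule took are not reported here.

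The fits were tested on simulated counts, drawn independently for each gene and library around the real gene means, with 200 genes changed by a known amount. The simulated values hold no correlation between genes or libraries, so the numbers of unchanged genes called may not carry over to the real data. Changes of 1 and 2 on the log2 scale were recovered for 37.8% and 73.5% of changed genes in PFC, with 3 unchanged genes called among 17658 genes tested. The shares were 41.5% and 66.3% in MDTH, with 5 unchanged genes called of 17528, and 26.5% and 57.6% in HPF, with 9 of 17745. For the interaction of MDTH against PFC they were 41.4% and 59.0%, with 7 unchanged genes called of 18043. For the difference between MDTH and PFC they were 68.4% and 78.8%, with 10 called of 18039.

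Library names carry a number beside the tissue. The numbers 44, 88 and 165 occurred in the high groups of all 3 tissues. The low groups held 130, 136 and 65 in PFC, 130, 163 and 6 in MDTH, and 163, 168 and 179 in HPF. Deviations from the group means were correlated between libraries that share a name number in different tissues, at 0.37 to 0.68 in all 11 pairs, against -0.41 to 0.34 in the 97 other pairs of different tissues. The name numbers were therefore taken to pair libraries across tissues, and a fit with the number as a correlated block was made for each interaction and tissue difference. High and low groups of 1 tissue share no name number. In PFC and MDTH the style of the library names also separated high from low performers completely, while the lanes were the same. In HPF the high libraries were on lanes 3 and 4 and the low libraries on lanes 4 and 5.

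The alternatives tried were another pseudocount, other filters on low values, rescaling and quantile normalization, library weights, all 18 libraries in 1 fit, the name number as a correlated block, the replicate number of the titles as a block, camera on ranks and with an estimated correlation, and each library left out in turn. A correction for transcript length and a lane term in HPF were chosen after seeing the data. All 18 libraries had high levels of the Y-linked gene Ddx3y, 2558 to 4846 normalized counts, with Xist at 0 to 29.7, so no library's sex differed from the rest.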

Results

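The series asked how gene expression in the brain differs between Diversity Outbred mice that performed well and poorly in short-term memory, with an orphan receptor of the thalamus named in its title. RNA sequencing gave 1 normalized count per gene for 18 libraries, 3 high and 3 low performers in each of PFC, MDTH and HPF. Estimated depth was 41156227 to 48838302 reads in PFC, 42941006 to 47535113 in MDTH and 76705451 to 88633852 in HPF, so the HPF values carry the least counting error.

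The receptor Gpr12 (ENSMUSG00000041468, GRCm38 chromosome 5, 146582398 to 146585239, minus strand, protein coding) was 1.91-fold higher in high than in low performers in MDTH. Gpr12 is a receptor without an established ligand that raises cAMP. The high libraries held 2833 ± 390 normalized counts (SD, n = 3) and the low libraries 1497 ± 365 (SD, n = 3), and every high library, at 2388, 3118 and 2993, lay above every low library, at 1917, 1325 and 1251. The log2 difference in MDTH was 0.94 (SE 0.18, 95% interval 0.50 to 1.37, limma adjusted p = 0.0135). Without replicate 3 of the low group the adjusted p was 0.0524, and over the 16 alternatives it ran from 0.000282 to 0.0524. The style of the library names separated high from low performers in MDTH. The Gpr12 difference therefore cannot be told apart from a possible difference in preparation.

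In PFC and HPF no difference in Gpr12 was detected. PFC held 671 ± 51.4 normalized counts in high and 626 ± 128 in low performers (SD, n = 3 each), a log2 difference of 0.12 (SE 0.17, 95% interval -0.29 to 0.53, adjusted p = 0.716) that turned to -0.03 without replicate 2 of the low group. HPF held 1446 ± 19.4 and 1548 ± 101 (SD, n = 3 each), a log2 difference of -0.10 (SE 0.09, 95% interval -0.30 to 0.11, adjusted p = 0.669). The difference in MDTH exceeded that in HPF by 1.03 on the log2 scale (SE 0.23, adjusted p = 0.00625), while its excess of 0.82 over PFC (SE 0.23, adjusted p = 0.0670) did not pass. Neither interaction value allows for the name numbers shared across tissues. Averaged over performance groups, Gpr12 was 3.16-fold higher in MDTH than in PFC and 1.36-fold higher than in HPF (adjusted p = 0.00370 for HPF). The excess over HPF came from the high performers, since among low performers the MDTH mean lay slightly below the HPF mean.

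**Figure D1:**
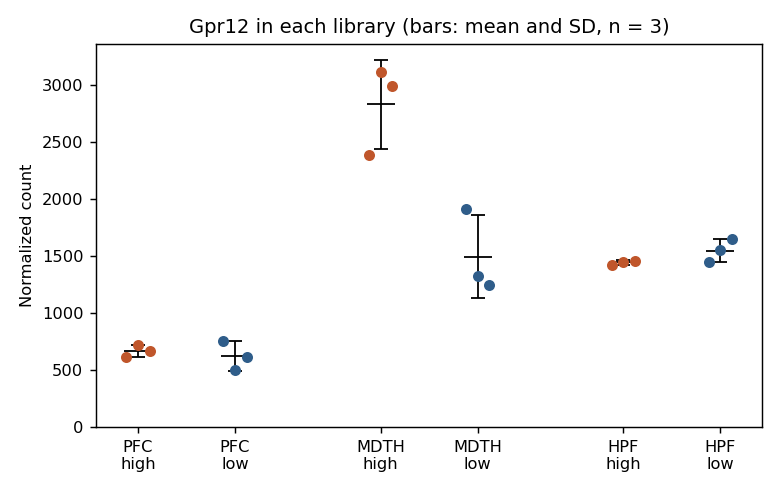
Normalized counts of Gpr12 in each of the 18 libraries, by tissue and performance group, with points for libraries and bars for the mean and SD of 3. The MDTH high libraries lie between 2388 and 3118 and the MDTH low libraries between 1251 and 1917, while the HPF means are 1446 and 1548 and the PFC means 671 and 626.

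Genes near Gpr12 on distal chromosome 5 moved in both directions in MDTH. Of 40 members tested, 10 were higher and 7 lower in high performers, and 13 and 7 were when adjusted over the list alone. Arpc1a, a subunit of the actin-nucleating complex, was higher by 0.84 on the log2 scale (adjusted p = 0.00278) and B3glct, a glycosyltransferase, by 0.84 (adjusted p = 0.00382). Hmgb1, a chromatin protein, fell by 0.65. The list did not pass as a whole (median log2 difference 0.16, camera adjusted p = 0.323). In PFC, 1 member was higher and 4 lower of 40 (3 and 4 adjusted over the list alone, median 0.05, camera adjusted p = 0.898). Among them Baiap2l1 fell from 1383 ± 254 to 48.6 ± 54.4 normalized counts (SD, n = 3 each, adjusted p = 0.0220) and Hmgb1 fell by 0.56 on the log2 scale (adjusted p = 0.0239). In HPF none of 41 passed by limma (0 adjusted over the list alone, median -0.04, camera adjusted p = 0.410). The smallest p there were those of Trrap (log2 difference 0.31, adjusted p = 0.243) and Rasl11a (-0.94, adjusted p = 0.275).

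In MDTH, the list of thalamic genes was higher and those of habenular and inhibitory neuron genes were lower in high performers by camera at the preset correlation. None of the 3 passed with an estimated correlation (adjusted p = 0.795 each). Mab21l2, a developmental gene, was 65.2-fold lower in high performers, at 6.10 ± 1.48 against 460 ± 82.2 normalized counts (SD, n = 3 each, adjusted p = 0.00135). Nos1, the neuronal nitric oxide synthase, fell from 3593 ± 1086 to 271 ± 41.4 (SD, n = 3 each, adjusted p = 0.00192), and the serotonin receptor Htr2a fell from 416 ± 74.4 to 20.9 ± 4.62 (SD, n = 3 each, adjusted p = 0.00192). The calcium-binding protein gene Calb1 was higher, at 12629 ± 182 against 6343 ± 528 (SD, n = 3 each, adjusted p = 0.00270). Across 17861 genes, 4470 passed, 2233 higher and 2237 lower, and 1237 of these changed over 2-fold. The 2 groups did not overlap for 44.2% of tested genes, where chance gives 10%. With 1 library left out, the MDTH count was 2469 and 2800 without replicates 2 and 3 of the high group and 2377 and 1839 without replicates 2 and 3 of the low group. Because name style separated high from low performers completely, performance and a possible difference in preparation cannot be told apart in the MDTH differences.

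The other genes named in MDTH by the smallest p covered enzymes, ion channels and small proteins. Aox4, an aldehyde oxidase gene, was 5.15-fold higher, and Cops9, Uqcc2, Smim7, Txn1 and Vbp1 were higher by 1.46, 1.18, 1.07, 1.03 and 0.93 on the log2 scale (adjusted p = 0.00216 to 0.00270). The globin gene Cygb fell by 3.32, the acid-sensing channel Asic4 fell by 3.64 and the potassium channel Kcnc4 by 2.06. Hpcal1, Atp2b4, Rbm12 and Tmem145 fell by 3.54, 2.47, 1.49 and 1.48 (adjusted p = 0.00192 to 0.00262 for these genes).

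Of 20 thalamic genes in MDTH, 12 were higher, 1 was lower and 7 did not pass (14 and 1 adjusted over the list alone). Ptpn3 was 3.45-fold higher (adjusted p = 0.00643), and Prkcd, a protein kinase abundant in relay neurons, rose by 1.94 on the log2 scale. Slc17a6, the vesicular glutamate transporter of thalamic neurons, was 1.51-fold higher (adjusted p = 0.00547, 0.508 with all 18 libraries in the fit), while the transcription factor Tcf7l2 fell by 0.49. The list's median was 0.91 (camera adjusted p = 0.000840, adjusted p = 0.795 with an estimated correlation). Of 10 habenular genes, 5 were lower and 5 did not pass (8 lower adjusted over the list alone, median -3.48, camera adjusted p = 0.000840, adjusted p = 0.795 with an estimated correlation). Pou4f1, a transcription factor of habenular neurons, stood at 10.4, 54.2 and 31.1 normalized counts in the high and at 169, 1335 and 3105 in the low libraries. Lmo3 fell by 2.71 on the log2 scale (adjusted p = 0.00270) and Irx2 by 2.07 (adjusted p = 0.0115, 0.161 with all 18 libraries).

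Of 15 inhibitory neuron genes in MDTH, 6 were lower, 1 was higher and 8 did not pass (7 and 1 adjusted over the list alone, median -1.23). Reln, an extracellular protein made by some interneurons, fell by 4.35 on the log2 scale (adjusted p = 0.00270), and Gad2, which makes GABA, stood at 9547 in replicate 1 of the low group against 2839 and 2457 in the others and 437 to 536 in the high group. The list passed with camera (adjusted p = 0.0436, adjusted p = 0.795 with an estimated correlation), but not without replicate 1 of the high group (adjusted p = 0.0655) nor on ranks (adjusted p = 0.121). Of 31 monoamine and acetylcholine receptor genes, 8 were lower and 2 higher (14 and 3 adjusted over the list alone, median -0.60, camera adjusted p = 0.0143, adjusted p = 0.795 with an estimated correlation). Htr1a fell by 3.47 (adjusted p = 0.00278), while the adrenergic receptor Adra1b rose by 1.02.

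Of the immediate-early genes, which neurons switch on within minutes of activity, 10 of 28 were lower in high performers in MDTH and 5 of 29 in PFC, and neither list passed with an estimated correlation (adjusted p = 0.795 and 0.929). In MDTH 2 were higher (11 lower and 3 higher adjusted over the list alone, median -0.81). Sik1 fell by 1.87 (adjusted p = 0.00270) and Nr4a2, which habenular neurons also express, by 4.33 (adjusted p = 0.00601). The camera adjusted p was 0.0436 (adjusted p = 0.795 with an estimated correlation), and it was 0.129 without replicate 1 of the high, 0.0803 without replicate 2 of the high, 0.0756 without replicate 1 of the low and 0.0583 without replicate 2 of the low group, and 0.0517 on ranks. In PFC 5 of 29 were lower and 0 higher (7 lower and 2 higher adjusted over the list alone, median -0.86, camera adjusted p = 0.00695, adjusted p = 0.929 with an estimated correlation). Klf4 fell by 1.76 (adjusted p = 0.0213) and Egr1 by 1.48 (adjusted p = 0.0270). Fos stood at 665, 645 and 752 normalized counts in the high and 6786, 5106 and 1586 in the low libraries of PFC. In HPF none of 29 passed by limma (0 adjusted over the list alone, median -0.03, camera adjusted p = 0.162), with Nr4a3 at a log2 difference of -1.12 (adjusted p = 0.228) and Gadd45b at -0.54 (adjusted p = 0.266).

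**Figure D2:**
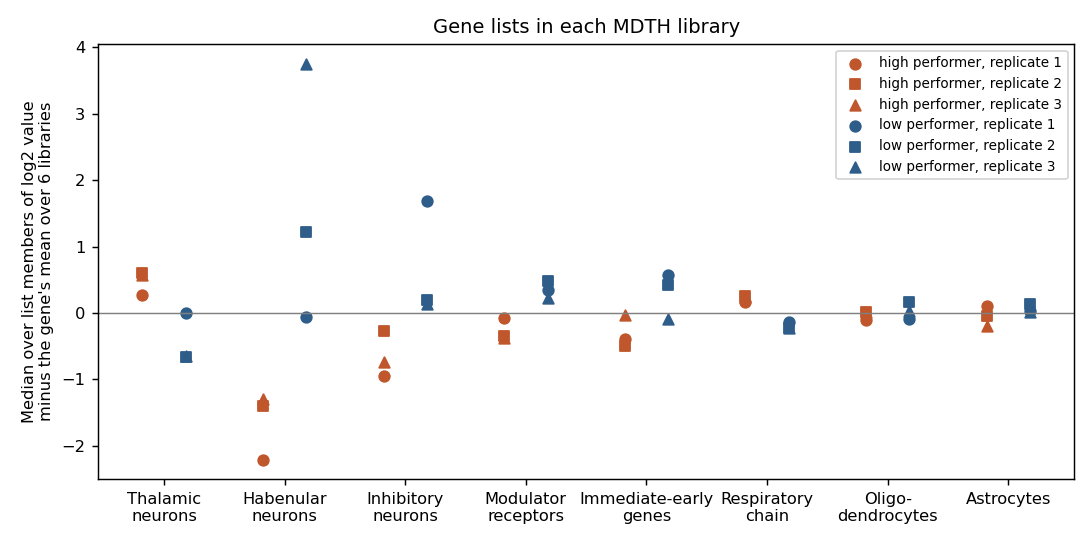
For 8 gene lists in the 6 MDTH libraries, each point is the median over the list of the log2 value minus the gene's mean over those libraries, with colour for performance and shape for replicate. The habenular list runs from -2.21 to -1.30 in high and from -0.06 to 3.75 in low libraries, and the inhibitory neuron list is highest, at 1.68, in replicate 1 of the low group.

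Of 34 orphan receptors tested in MDTH, 7 were lower and 4 higher in high performers (8 and 5 adjusted over the list alone), and the list did not pass as a whole (median -0.15, camera adjusted p = 0.535). Gpr101 fell from 822 ± 276 to 29.2 ± 20.1 normalized counts (SD, n = 3 each, adjusted p = 0.00371) and Gpr139 by 4.29 on the log2 scale (adjusted p = 0.00827). In PFC the list of 34 had a median of 0.10 (camera adjusted p = 0.354), with Gpr75 at -0.42 (adjusted p = 0.142). In HPF none of 34 passed by limma over all genes, while 2 higher and 3 lower passed adjusted over the list alone. There Gpr161, a receptor of the primary cilium, was at 3197 ± 384 in high and 740 ± 258 in low performers (SD, n = 3 each, adjusted p = 0.0686). The HPF list had a median of -0.06 and a mean of 0.11 (camera adjusted p = 0.409).

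Genes of cAMP signalling moved both ways in MDTH, with 7 of 31 higher and 5 lower (11 and 9 adjusted over the list alone, median -0.03, camera adjusted p = 0.912). Prkar2a, a regulatory subunit of protein kinase A, fell by 0.96 (adjusted p = 0.00342) and the phosphodiesterase Pde1a by 2.16 (adjusted p = 0.00833), while the adenylyl cyclase Adcy1 rose by 1.26. In PFC 2 were higher and 1 lower of 31 (4 and 1 adjusted over the list alone, median 0.11, camera adjusted p = 0.0874). The phosphodiesterase Pde4b was higher there by 0.44 (adjusted p = 0.0290) and Prkar2b by 0.45 (adjusted p = 0.0397). In HPF none of 31 passed by limma (0 adjusted over the list alone, median 0.10, camera adjusted p = 0.145), with Rapgef3 at 0.65 (adjusted p = 0.205) and Prkaca at -0.29 (adjusted p = 0.263).

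In PFC, 29 of 72 nuclear-encoded respiratory chain genes were higher and 9 of 13 mitochondrially encoded genes lower in high performers, while neither list passed with an estimated correlation (adjusted p = 0.929 and 0.337). Rpl22l1, a paralog of a ribosomal protein, was 3.87-fold higher, at 2467 ± 172 against 636 ± 28.1 normalized counts (SD, n = 3 each, adjusted p = 0.00174). The cap-binding translation factor Eif4e was 1.92-fold higher (adjusted p = 0.00893). Ewsr1, an RNA-binding protein gene, fell from 15985 ± 939 to 7312 ± 610 (SD, n = 3 each, adjusted p = 0.00893), and Sdc3, a neuronal heparan sulfate proteoglycan gene, from 16144 ± 1374 to 8363 ± 338 (SD, n = 3 each, adjusted p = 0.00958). Across 17991 genes, 1053 passed, 579 higher and 474 lower, 166 of them over 2-fold, and the groups did not overlap for 30.9%, where chance gives 10%. As in MDTH, name style separated the groups completely, so performance and a possible difference in preparation cannot be told apart in the PFC differences.

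Leaving out 1 library lowered the number of PFC genes that passed in 5 of 6 fits. Of 36 genes that the naming rule took and that passed in PFC, 25, 5 and 3 still passed without replicates 1, 2 and 3 of the high group and 25, 36 and 3 without replicates 1, 2 and 3 of the low group. The count of all genes was 205, 17 and 7 without replicates 1, 2 and 3 of the high group and 278, 1306 and 9 without replicates 1, 2 and 3 of the low group. The log2 difference of Ewsr1 ran from -1.19 to -1.07 over these fits. The other genes named in PFC were Atp6v1h, Hnrnpa0, Smim7 and Ndfip1, higher by 0.77, 0.76, 0.85 and 0.69 on the log2 scale, and Snrpd3, Clip3, Atf7, Nfia, Paf1 and Zfp579, which fell by 0.90, 0.96, 0.97, 0.92, 0.87 and 1.09 (adjusted p = 0.00893 to 0.0112). The antisense gene BC023719 was listed at 0 in every low library and at 421, 518 and 1064 in the high libraries. With the use of strand not stated, the values of BC023719 are uncertain, as are those of the pseudogenes Pgam1-ps2 (2.48-fold higher) and Llph-ps1 (84.5 ± 18.6 against 0.368 ± 0.638, SD, n = 3 each), whose reads resemble those of their parent genes. BC023719 and Llph-ps1 are among 26 genes present in some libraries and absent in others in every tissue. Libraries that share a name number had the same state of these 2.

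Of 72 nuclear-encoded respiratory chain genes in PFC, 29 were higher, 1 was lower and 42 did not pass (41 and 1 adjusted over the list alone, median 0.31). Atp5e, a subunit of ATP synthase, was 2.23-fold higher (adjusted p = 0.00893) and Atp5g3 1.58-fold (adjusted p = 0.0112). The camera adjusted p was 8.08e-16, and the adjusted p was 0.929 with an estimated correlation. Of 13 mitochondrially encoded genes, 9 were lower and 1 was higher (10 and 2 adjusted over the list alone, median -0.78, camera adjusted p = 2.14e-05, adjusted p = 0.337 with an estimated correlation). The subunit gene mt-Atp8 fell by 0.91 (adjusted p = 0.00958), while mt-Nd4l was higher by 1.21 (adjusted p = 0.0136). All genes whose symbol begins with mt-, a set not limited to these 13, took 5.43% ± 0.172 of all counts in high and 8.47% ± 0.279 in low performers (SD, n = 3 each). In MDTH, 48 of the 72 nuclear-encoded genes were higher and 0 lower (52 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 8.51e-17, adjusted p = 0.795 with an estimated correlation), with Ndufa4 2.18-fold higher (adjusted p = 0.00270) and Cox7a2 1.70-fold (adjusted p = 0.00278). Of the 13 mitochondrially encoded genes 2 were higher and 4 lower in MDTH (2 and 7 adjusted over the list alone, camera adjusted p = 0.160). All genes whose symbol begins with mt- took 5.90% ± 0.444 of counts in high and 7.72% ± 1.06 in low performers of MDTH (SD, n = 3 each).

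Of 63 ribosomal protein genes in PFC, 10 were higher and 1 was lower (17 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 0.00209, adjusted p = 0.929 with an estimated correlation), among them Rps20 by 1.14 (adjusted p = 0.0185) and Rps21 by 0.76 (adjusted p = 0.0185). Of 14 GABA receptor genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 0.00662, adjusted p = 0.929 with an estimated correlation), with Gabra2 1.52-fold higher (adjusted p = 0.0268). That list did not pass without replicate 2 of the low group (adjusted p = 0.0792). Of 15 glucocorticoid and stress genes, 1 was lower (4 adjusted over the list alone, median -0.32, camera adjusted p = 0.0491, adjusted p = 0.929 with an estimated correlation). Pdk4, a brake on glucose oxidation, fell by 1.08 (adjusted p = 0.0196) and Sgk1 was at -1.08 (adjusted p = 0.0658). The list's adjusted p was 0.398 without replicate 2 of the high and 0.238 without replicate 2 of the low group, and 0.0651 on ranks.

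Microglial and choroid plexus lists were lower in PFC of high performers by camera at the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.929 each), and the choroid list did not follow the groups. Of 14 microglial genes, 3 were lower (6 adjusted over the list alone, median -0.38, camera adjusted p = 0.00880, adjusted p = 0.929 with an estimated correlation), where P2ry12 fell by 0.61 (adjusted p = 0.0288) and the complement gene C1qa by 0.89 (adjusted p = 0.0340). The list's adjusted p was 0.0903 without replicate 1 of the high and 0.0999 without replicate 2 of the low group. Of 15 genes of choroid plexus and ependyma none passed by limma (0 adjusted over the list alone, median -2.04, camera adjusted p = 0.0297, adjusted p = 0.929 with an estimated correlation), with Ccdc153 at -2.54 (adjusted p = 0.215) and Otx2 at -2.06 (adjusted p = 0.316). That list stood at least 1.92 above its mean in replicate 1 of the high and replicates 2 and 3 of the low group, and at -1.15 to -2.63 in the other libraries. Its adjusted p was 0.190 and 0.163 without replicates 2 and 3 of the high and 0.205 and 0.185 without replicates 2 and 3 of the low group. Replicate 2 of the low group also stood 1.17 above the mean in oligodendrocyte genes and 2.03 in blood genes.

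PFC and MDTH shared many changed genes. Among 17223 genes tested in both, 423 were higher in both, against 73.3 for independent lists, and 337 were lower in both, against 58.7, while 9 moved in opposite directions. Rpl22l1 was 2.76-fold higher in MDTH (adjusted p = 0.00192) and Eif4e 1.79-fold (adjusted p = 0.00270). The fold changes of PFC and MDTH had a Spearman correlation of 0.51 across genes, which are not independent replicates, against -0.06 for PFC and HPF and 0.01 for MDTH and HPF. PFC and MDTH libraries share name numbers, so the 2 comparisons are not independent. Signed by their PFC direction, the 760 shared genes had a median log2 difference of 0.60 in PFC, 0.65 in MDTH and -0.02 in HPF.

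**Figure D3:**
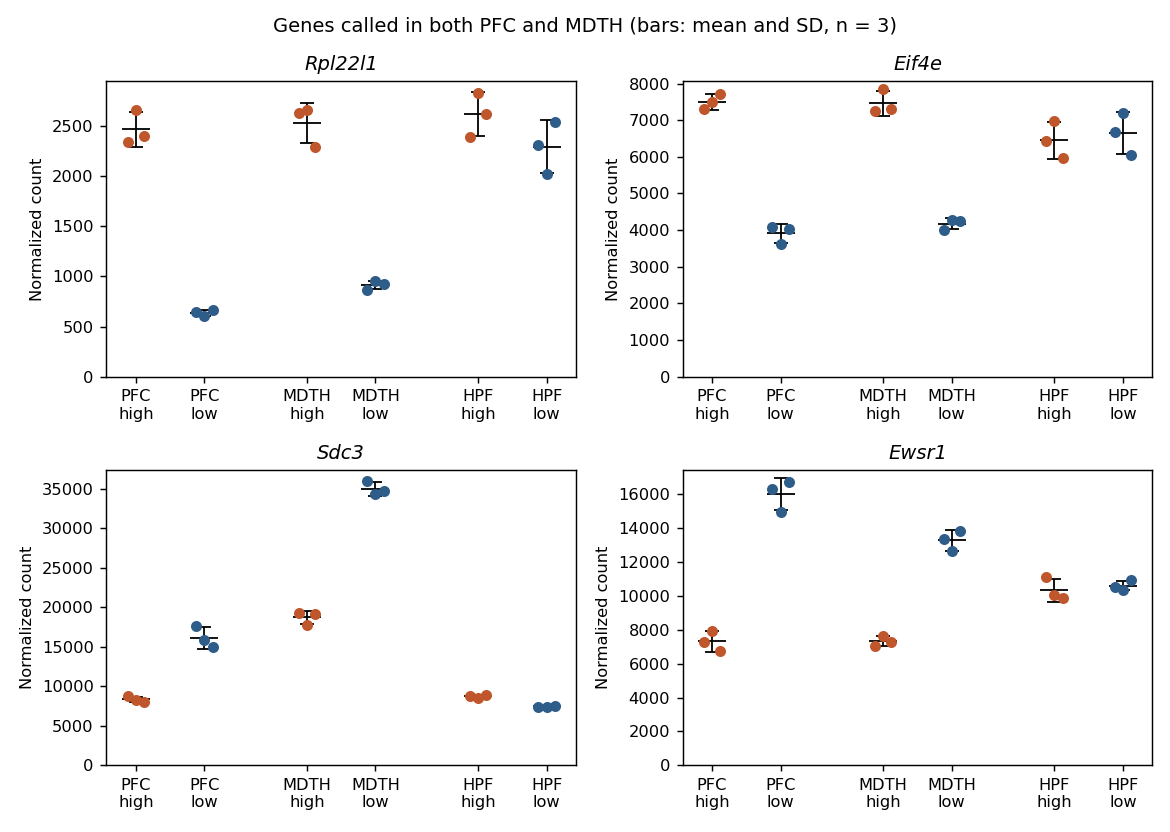
Normalized counts of 4 genes that passed in PFC and MDTH, in all 18 libraries by tissue and performance group, with points for libraries and bars for the mean and SD of 3. Rpl22l1 is at 2467 and 636 in high and low PFC and 2528 and 913 in high and low MDTH, while its HPF groups overlap.

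Tested alone, HPF had 3 genes that passed between high and low performers, against 265 with all 18 libraries in 1 fit and 246 with the name number as a correlated block in that fit. Iyd, a deiodinase that this tissue expressed far above PFC, fell from 466 ± 69.3 to 68.0 ± 7.68 normalized counts (SD, n = 3 each, adjusted p = 0.0181). The pseudogene Actg-ps1 was higher, at 505 ± 188 against 23.6 ± 2.80 (SD, n = 3 each, adjusted p = 0.0198), and so was Gm8399, at 1238 ± 293 against 92.2 ± 9.51 (SD, n = 3 each, adjusted p = 0.00727), a predicted gene chosen after its values were seen. These were the 3 of 18082 genes that passed, while 2399 had an unadjusted p below 0.05 by limma and the groups did not overlap for 3625 genes, where chance gives 10% of those tested. With the lane as a term the adjusted p was 0.243 for Iyd and 0.170 for Actg-ps1, and the 2 were lost in 4 of the 6 fits with a library left out. That removal gave 0 genes without replicate 1 of the high, 2 without its replicate 2, 6 without its replicate 3, and 7 and 15 without replicates 1 and 2 of the low group.

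Other HPF genes with small p did not pass. Fibcd1, a marker of dorsal CA1, stood at 6196 ± 1134 against 1411 ± 512 (SD, n = 3 each, adjusted p = 0.0703), and Rin2 had a log2 difference of 0.71 (SE 0.08, adjusted p = 0.0703). Rplp0-ps1, a pseudogene, stood at 61.3 ± 36.9 against 0.873 ± 0.333 (SD, n = 3 each, adjusted p = 0.0636). Nvl, Ak5 and Hs3st4 had log2 differences of -2.21, -0.93 and -1.59 (adjusted p = 0.0527 each).

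By camera at the preset correlation, genes of synaptic vesicle release were lower in HPF of high performers while astrocyte, vascular and microglial lists were higher. None of these passed with an estimated correlation (adjusted p = 0.577 to 0.580). Replicate 3 of the high group had the lowest vesicle score, -0.42, and the highest scores in those 3 lists. None of 25 passed over all genes by limma, while 13 lower and 1 higher passed adjusted over the list alone (median -0.37, camera adjusted p = 6.90e-08, adjusted p = 0.577 with an estimated correlation). Vamp1 and Snap25, which fuse vesicles with the membrane, had log2 differences of -0.90 (adjusted p = 0.135) and -0.85 (adjusted p = 0.153). Of the 72 nuclear-encoded respiratory chain genes 66 lay below 0, against the direction in PFC and MDTH, with no member passing by limma (0 adjusted over the list alone, median -0.11, camera adjusted p = 7.65e-08, adjusted p = 0.109 with an estimated correlation). Atp5g1 was at -0.49 (adjusted p = 0.185) and Cox5a at -0.26 (adjusted p = 0.244). All 13 mitochondrially encoded genes lay above 0 (0 adjusted over the list alone, median 0.42, camera adjusted p = 0.00103, adjusted p = 0.577 with an estimated correlation), with mt-Cytb at 0.59 (adjusted p = 0.287) and mt-Atp8 at 0.42 (adjusted p = 0.376). All genes whose symbol begins with mt- took 7.44% ± 1.08 of counts in high and 5.68% ± 0.884 in low performers of HPF (SD, n = 3 each). Ribosomal protein genes had a median of 0.08 (63 tested, 0 adjusted over the list alone, camera adjusted p = 0.00567, adjusted p = 0.637 with an estimated correlation). Their adjusted p was 0.987 with the direction turned without replicate 3 of the high, 0.149 without replicate 1 of the low and 0.0729 without replicate 2 of the low group. Rps3 was at 0.21 (adjusted p = 0.391) and Rps26 at -0.63 (adjusted p = 0.434), the latter turning to 0.005 with a lane term.

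By camera at the preset correlation, thalamic, striatal and choroid lists were higher in HPF of high performers, mainly through replicate 2 of the high group. No member passed by limma, and no list passed with an estimated correlation (adjusted p = 0.577 to 0.580). The thalamic list had a median of 0.93 (20 tested, 0 adjusted over the list alone, camera adjusted p = 0.000142, adjusted p = 0.580 with an estimated correlation), although Prkcd was at -1.90 (adjusted p = 0.228) and Amotl1 at 0.94 (adjusted p = 0.245). The striatal list had a median of 0.59 (14 tested, 1 higher adjusted over the list alone, camera adjusted p = 0.00224, adjusted p = 0.577 with an estimated correlation), with Ppp1r1b at 0.84 (adjusted p = 0.191) and the opioid precursor gene Penk at 0.62 (SE 0.21). Choroid plexus and ependymal genes had a median of 1.26 (15 tested, 0 adjusted over the list alone, camera adjusted p = 0.00222, adjusted p = 0.580 with an estimated correlation), with Prlr at 1.83 (adjusted p = 0.338) and Ttr at 2.34 (adjusted p = 0.435). Replicate 2 of the high group stood apart in these, at 1.33 for the thalamic, 0.89 for the striatal and 2.72 for the choroid list, and without it the adjusted p was 0.182 for the striatal and 0.205 for the choroid list. The thalamic scores of replicates 1 and 3 of the high group, -0.16 and -0.07, still lay above those of the low group, -0.78 to -0.31. Glucocorticoid and stress genes had a median of 0.26 (15 tested, 0 adjusted over the list alone, camera adjusted p = 0.00790, adjusted p = 0.577 with an estimated correlation, and 0.0918 without replicate 2 of the high group), with the metallothioneins Mt2 at 0.88 (adjusted p = 0.248) and Mt1 at 0.77 (adjusted p = 0.326).

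Vascular genes in HPF had a median of 0.58 (16 tested, 0 adjusted over the list alone, camera adjusted p = 1.03e-05, adjusted p = 0.577 with an estimated correlation), with Slco1a4 at 0.60 (adjusted p = 0.227) and Cdh5 at 0.63 (adjusted p = 0.292). Astrocyte genes had a median of 0.35 (15 tested, 3 higher adjusted over the list alone, camera adjusted p = 1.67e-05, adjusted p = 0.577 with an estimated correlation), with Fgfr3 at 0.60 (adjusted p = 0.205) and Gjb6 at 0.73 (adjusted p = 0.221). Microglial genes had a median of 0.26 (14 tested, 0 adjusted over the list alone, camera adjusted p = 0.00279, adjusted p = 0.580 with an estimated correlation), with Csf1r at 0.39 (adjusted p = 0.358) and Cx3cr1 at 0.45 (adjusted p = 0.374). Replicate 3 of the high group held the highest score in each, 0.82, 0.59 and 0.42, and the microglial adjusted p was 0.140 without it and 0.0606 without replicate 1 of the low group.

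**Figure D4:**
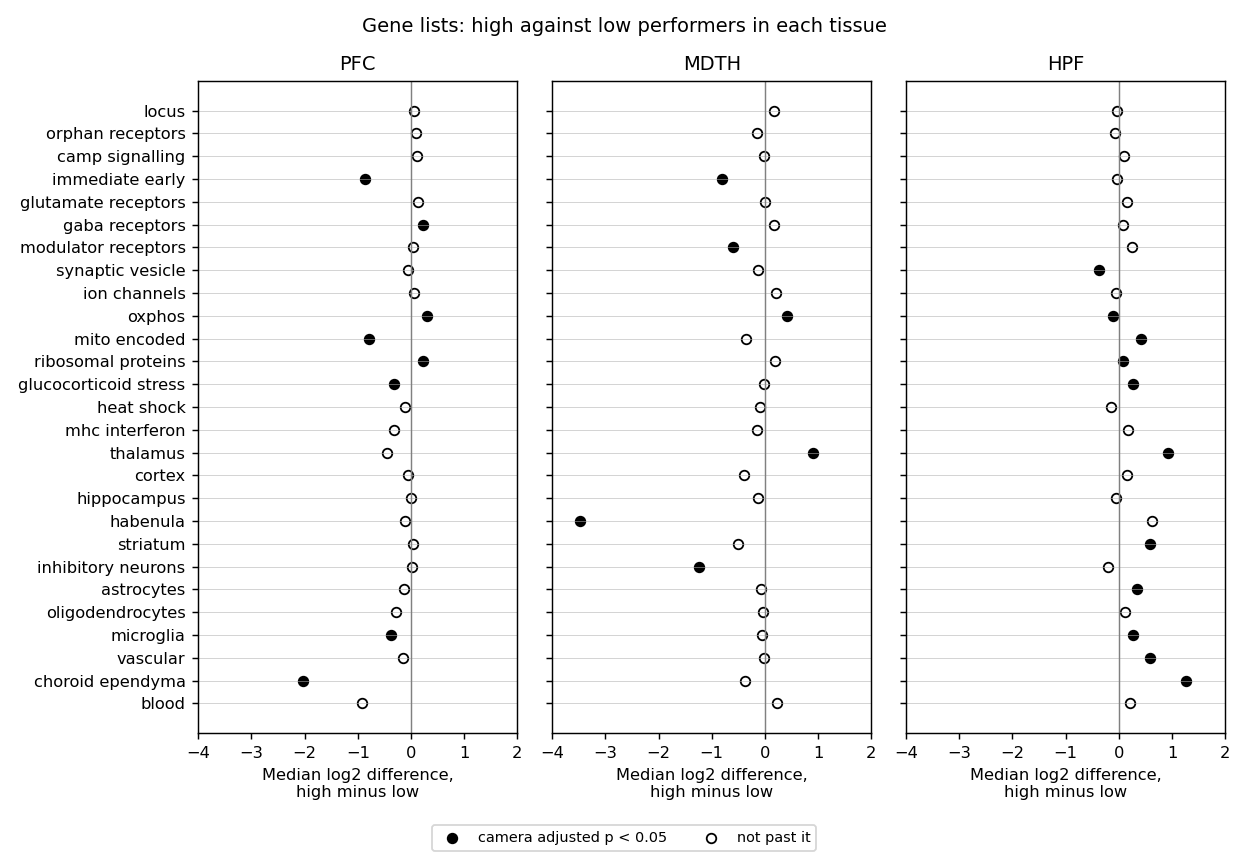
Median log2 difference, high minus low, of 27 gene lists in PFC, MDTH and HPF, with filled points for lists past a camera adjusted p of 0.05 at the preset correlation. The respiratory chain list (oxphos) is at 0.31 in PFC, 0.41 in MDTH and -0.11 in HPF, and the habenular list is at -3.48 in MDTH.

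Tested as an interaction over 18254 genes, the difference between high and low performers in MDTH departed from that in HPF for 3476 genes, 1920 more positive and 1556 more negative in MDTH. Sdc3, which had fallen in high performers in MDTH and PFC, differed from HPF by -1.13 in MDTH (adjusted p = 1.10e-05), and Txn1, a thioredoxin, by 1.14 (adjusted p = 1.22e-05). Between HPF and PFC the difference departed for 1669 genes, 615 more positive and 1054 more negative in HPF, with Rpl22l1 at -1.76 (adjusted p = 1.47e-05) and Ewsr1 at 1.09 (adjusted p = 0.000108). Between MDTH and PFC it departed for 623 genes, 159 more positive and 464 more negative in MDTH, and for 1034 with the name number as a correlated block. Nos1 led these at -3.96 (adjusted p = 2.73e-06), followed by Htr2a at -4.87 (adjusted p = 3.31e-06). The MDTH and PFC count fell to 402, 403, 344 and 278 without replicates 2 and 3 of the MDTH high and 3 and 2 of the MDTH low group and to 408 without replicate 2 of the PFC high group. It rose to 964 and 1004 without replicate 1 of the MDTH high and low groups. The HPF and PFC count was 949 and 1047 without replicates 2 of the PFC high and 3 of the PFC low group, and 896 and 909 without replicates 3 of the HPF high and 1 of the HPF low group. The name styles that separate high from low performers in PFC and MDTH do not occur in HPF. Both interactions with HPF therefore cannot be told apart from a possible difference in preparation. The HPF low group also shares only number 163 with MDTH and no number with PFC.

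The 3 tissues differed from one another in the genes fixed as regional markers. All 20 thalamic genes were higher in MDTH than in PFC (median 4.41) and than in HPF (median 4.18), among them Amotl1, at 4.05 and 4.06, with Lef1 at 4.41 and Prkcd at 6.91 against PFC. The cortical transcription factor genes Tbr1, Neurod6 and Emx1 were at -7.00, -5.79 and -6.15 in MDTH against PFC, where 12 of 20 cortical genes were lower and 5 higher. Of 20 hippocampal genes, 18 were higher in HPF than in PFC (median 3.62) and 18 were lower in MDTH than in HPF. Among them the dentate gyrus gene Prox1 was at 3.94 and Iyd at 5.59 in HPF against PFC, and Neurod2 at -6.26 in MDTH against HPF. By limma 7428 genes differed between MDTH and PFC (3711 higher, 3717 lower), 10607 between MDTH and HPF (5312 higher, 5295 lower) and 8311 between HPF and PFC (3987 higher, 4324 lower). HPF libraries have other names and lanes than those of PFC and MDTH, so the tissue and a possible batch cannot be told apart there.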

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

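The tests on habenular tissue, on splits that respect shared name numbers, on a Gpr12 effect of equal size in the tissues, on the genes shared by PFC and MDTH and on genes present in some libraries and absent in others were chosen after the results were seen.

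The difference between high and low performers departed between tissues by the interaction test for 3476 genes of MDTH against HPF, 1669 of HPF against PFC and 623 of MDTH against PFC. Log2 values are the first tissue minus the second. Gpr12 was at 1.03, Cygb at -3.38, BC030500 at -4.09, Sdc3 at -1.13, Nos1 at -3.26 and Txn1 at 1.14 for MDTH against HPF. Sdc3 was at 1.18, Rpl22l1 at -1.76, Arpc4 at -0.92, Ewsr1 at 1.09 and Psmb4 at -0.86 for HPF against PFC. Nos1 was at -3.96, Htr2a at -4.87, Cygb at -3.07, Htr1a at -3.85 and Lancl3 at -3.56 for MDTH against PFC. The name styles that separate high from low performers in PFC and MDTH do not occur in HPF. Both interactions with HPF therefore cannot be told apart from a possible difference in preparation. Of 100 drawn splits that reassigned high and low in each tissue alone, 1 gave as many genes for MDTH against HPF (the real one, highest other 3131) and 1 for HPF against PFC (highest other 1280), but these splits ignore the name numbers shared across tissues. Among the 28 splits that kept libraries with a shared number on one side, 1 gave as many genes for HPF against PFC. It was the real one (highest other 2), a share under 0.05. The 28 splits hold only the 10 possible groupings of the PFC libraries. They were also chosen after the results were seen, so chance was not firmly excluded. For MDTH against HPF only 16 such splits exist (real 3476, highest other 1), too few for a share under 0.05, as are the 16 for MDTH against PFC (real 623, highest other 1). For MDTH against PFC 8 of the 100 drawn splits gave as many, and chance was not excluded. The highest of them, 6548 genes, was several times the real count, which points to a structure of the samples and may reflect splits that turn the difference shared by PFC and MDTH into an interaction.

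In MDTH, the thalamic list was higher and the habenular and inhibitory neuron lists lower in high performers, with Gpr12 higher too, but each list lost its call with an estimated correlation (adjusted p = 0.795) and the inhibitory list also on ranks (adjusted p = 0.121). A Gpr12 effect of equal size in all tissues was not seen in HPF. There the upper limit of 0.11 lay below the MDTH interval of 0.50 to 1.37. An equal effect cannot be excluded, since the HPF low group shares only number 163 with MDTH and HPF has other name styles. The PFC limit of 0.53 overlapped the MDTH interval, and the PFC interaction did not pass. More habenular tissue in the low libraries stays open: all 3 lay above every high library by more than 1 in the habenular median, which restates the difference that raised the explanation and lends it no support. Whether habenular tissue alone brought the inhibitory neuron genes also stays open, since their median excess of 0.85 (SE 0.39 over genes) in low replicate 1 over low replicate 3 compares 1 library with 1. A larger share of thalamic neurons stays open for Gpr12, whose difference lay at percentile 79.6 of 843 other genes at least 2-fold higher in MDTH than in PFC and HPF. Gpr12 was higher in MDTH than in HPF by only 0.44 on the log2 scale, under 2-fold, and so lies outside that set. The set was not limited to genes of thalamic neurons, with 185 higher and 111 lower in high performers. Its median was only 0.24 and its middle 95% ran from -3.36 to 1.99. That range is too wide to tell a share of neurons from a change of Gpr12 that goes with performance. Library preparation also stays open for Gpr12 and for these lists, because name style separated high from low libraries in MDTH.

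Genes that passed in the same direction in PFC and MDTH, 760 of them, formed a second pattern. An effect carried by the animals into every tissue was not seen in HPF. The median HPF difference of these genes, signed by the PFC direction, was -0.0184 (SE 0.0186 over genes, not libraries). Such an effect cannot be excluded, since the HPF low group shares only number 163 with MDTH and no number with PFC. That 1 low number scored -0.30 in MDTH and 0.04 in HPF. A trend with transcript length was excluded, since 97.8% still passed in both tissues after the length correction. Library preparation stays open and cannot be told apart from performance, because only 2 of the 4 possible combinations of library name style and performance occur in PFC and MDTH. The share of low values that were whole reads also separated high from low performers in PFC. In MDTH the groups overlapped, with 41.7% in high replicate 1 and 44.5% in low replicate 1. Rescaling and quantile normalization gave 1067 and 1256 genes in PFC and 4484 and 4585 in MDTH, near the counts reported. Both start from the deposited values, so the authors' normalization stays open too, as does a performance effect limited to these 2 tissues.

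In each tissue 26 genes had libraries with at least 50 normalized counts and libraries with at most 5, among them BC023719. Libraries that share a name number in different tissues agreed in state for a median of 92.3% of these genes (84.6% to 100% in 11 pairs), against 50% in the 97 other pairs (permutation p = 4e-04 with 10000 permutations), so variants inherited from the founder strains may set the state. Of the 26 genes 88.5% are annotated as pseudogenes, against 5.90% of tested genes, so reads of parent genes that carry a variant could also be placed on a copy. Both explanations held in their tests and are not exclusive. For genes of this kind, a difference between 3 high and 3 low libraries may reflect which animals fell in each group, and no biological explanation tied to performance was tested.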

How the results depend on the processing

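The length correction, the lane term and their values were chosen after the data were seen. Of the comparisons of single named genes with an alternative, 2585 kept their direction and side of the threshold, 175 no longer passed, 47 newly passed and 2 reversed, Gpr12 in PFC (-0.0336 without replicate 2 of the low group, the lowest of a range up to 0.26 with a library left out) and Rps26 in HPF (0.00503 with lane as a term). The losses gathered in PFC, where 5, 3 and 3 of 36 genes still passed without replicates 2 and 3 of the high and 3 of the low group. The PFC count of 1053 genes became 4303 with library weights, 2537 with all 18 libraries in 1 fit and 2506 when that fit also took the name number as a correlated block, and ran from 7 to 1306 with a library left out. The MDTH count of 4470 ran from 1839 to 4223. The HPF count of 3 became 11 without a filter, 6 at a mean of at least 100, 7 with quantile normalization, 265 with all 18 libraries, 246 with the block added to that fit and 6 with a lane term, and ran from 0 to 15. With a library left out, interactions ran from 278 to 1004 for MDTH against PFC (1034 with the correlated block), 896 to 1818 for HPF against PFC and 2511 to 3608 for MDTH against HPF, and tissue differences from 6894 to 7608, 7590 to 8280 and 10036 to 10366. The cause was not tested. Lists that passed by camera, 8 in PFC, 6 in MDTH and 11 in HPF, came to 0 in each with an estimated correlation, and ran from 4 to 15, 4 to 7 and 8 to 15 with a library left out. By fry, which does not compare a list with other genes, the respiratory chain list passed in PFC, MDTH and HPF (fry adjusted p = 0.0418, 0.0176 and 0.0138). In PFC the mitochondrially encoded (0.00120) and thalamic lists (0.0442) also passed by fry, and in MDTH the monoamine and acetylcholine receptors (0.0315). No other list passed by fry. Between fits of the same form, the correlated block moved only the count for MDTH against PFC interactions by over 1.5 times.

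Pairing high and low libraries by the replicate number of the titles had no basis in the values, with correlations of -0.15 to 0.12 in same-numbered pairs and -0.10 to 0.13 in others. The replicate block gave 0 genes in PFC, 2425 in MDTH and 0 in HPF. Tests that need whole reads, edgeR and DESeq2, were not run, since in every library a part of the low values was not whole. Depth limits HPF least, and its simulated 2-fold changes were recovered for 26.5% of genes, the lowest share of the 3 tissues. The simulated spread of each gene was taken over all 18 libraries, so that share does not measure the spread within HPF. In the real fits the median SE was 0.172 in HPF, 0.182 in PFC and 0.174 in MDTH.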

Other observations

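The dorsal-ventral prediction was written before its values were examined, except for Fibcd1, which had been seen. The likeness of MDTH 6 and PFC 65 was found, and the splits that respect shared name numbers were chosen, after the results were seen.

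Beyond the regional markers, the tissues differed in cell-type and pathway genes. Of 18 inhibitory neuron genes, 17 were lower in MDTH than in PFC and 0 higher (median -3.83), and 15 were lower than in HPF. Of 18 oligodendrocyte genes, 16 were higher in MDTH than in HPF and 14 were lower in HPF than in PFC (median -1.19). Of 15 astrocyte genes, 10 were higher in MDTH than in PFC (median 0.70), and of 14 microglial genes 13 were lower in MDTH than in HPF (median -0.58). Of 29 immediate-early genes, 18 were lower in MDTH than in PFC (median -1.33) and 16 were lower in HPF than in PFC (median -0.81). Of 63 ribosomal protein genes, 45 were higher in HPF than in PFC and 52 lower in MDTH than in HPF. Of 25 synaptic vesicle genes, 19 were lower in HPF than in PFC (median -0.72). All HPF contrasts are confounded with the other names and lanes of its libraries.

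For the differences between tissues, 1 of 100 drawn splits gave as many genes in each case, the real one. The highest others were 3313 for MDTH against PFC (real 7428), 5435 for MDTH against HPF (real 10607) and 4088 for HPF against PFC (real 8311). Among splits that parted every pair of libraries with a shared number, as the real one does, 1 of 48, 1 of 48 and 1 of 80 gave as many (highest others 4149, 5266 and 3194), so chance was excluded. Within a tissue, 6 libraries allow 10 splits, too few for a share under 0.05. In PFC 1 split gave as many genes as the real 1053 (highest other 26), in MDTH 1 as many as 4470 (highest other 6), and in HPF 4 as many as 3 (highest other 10). For the lists, 7 splits gave as many as the real 8 in PFC (highest other 12), 7 as many as 6 in MDTH (highest other 9) and 4 as many as 11 in HPF (highest other 16). The number of lists was thus no larger for performance than for other groupings of the same libraries.

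Fibcd1, a marker of dorsal CA1, was 4.52-fold higher in high performers in HPF without passing, which raised the hypothesis that the dissections differed in position along the dorsal-ventral axis. The values argue against more dorsal tissue in the high libraries as the whole cause, since 8 ventral genes had a median log2 difference of 0.65 (SE 0.28 over genes, not libraries) in high performers, against the fall it predicts. The ventral genes Grp, at 1.44, and Nr2f2, at 0.57, were both higher, and the 2 dorsal genes other than Fibcd1 had a median of 0.08. None of these genes passed by limma. Replicate 2 of the high group also had raised thalamic, striatal and choroid genes, and the part of such other tissue in the ventral values was not tested.

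In the state of the 26 genes that were present in some libraries and absent in others, MDTH 6 and PFC 65 agreed for 96.2%, as closely as libraries that share a number, while no other pair with different numbers exceeded 80.8%. That these 2 libraries came from 1 animal may be set as a hypothesis, against the median of 92.3% for libraries that share a number. Their deviations from the group means correlated at 0.34, the highest of the 97 pairs with different numbers and just below the lowest pair with a shared number, 0.37. The labels do not say whether the numbers stand for animals, and no library was moved or left out because of it.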
